A study of Syntrichia ruralis with 8 samples.

How the data were processed

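Transcript levels in gametophytes (the leafy haploid plants) of the desiccation-tolerant moss Tortula ruralis were measured on 8 2-colour cDNA arrays. Each array set poly(A) RNA of treated gametophytes against that of hydrated gametophytes, with 1 dye per channel, labelled with a commercial detection kit per the labels. The treatments were slow drying, and rapid drying followed by rehydration, and each was measured in total RNA and in polysomal RNA, with 2 arrays per combination and the dyes exchanged between them. The design text says that the 2 arrays of a combination came from 2 separate RNA preparations, each pooled from many plants, and that polysomal and total RNA came from separate samples. Replicate numbers were assigned here, 1 to the array with the treated RNA in Cy3 and 2 to the array with it in Cy5, and pair no samples across groups.

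The deposited scanner files give, per channel and spot, the intensity of the spot and of its local background, in arbitrary scanner units with no normalization, per the file headers. A spot flag of another kind, deposited beside these values, runs from 0 to 3. The flag's meaning, the scanner and the image software are not given in the sources used here. In a separate table the authors give 1 ratio per clone and array, treated over hydrated, with the spots combined. Its values show that each array was divided so that the median of 4 ribosomal protein control clones is 1. The scanner files were the starting point here, and the authors' ratio table was used as an alternative.

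Both channels were corrected for background by the normexp method with an offset of 50, and the log2 ratio of treated over hydrated signal was taken per spot. Global loess (span 0.3, 4 iterations) then removed the trend of the ratio with signal within each array, which sets the typical clone at 0. The 3 spots of each clone were averaged. One model was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3, with a coefficient for each of the 4 comparisons and a term for the dye, followed by empirical Bayes moderation (3 residual degrees of freedom per clone and 6.41 in total). Contrasts between coefficients gave the 4 differences between comparisons. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over the 768 clones, with calls at an adjusted p under 0.05. These p-values measure the spread between these samples, pooled over all 8 arrays.

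Because loess sets the typical clone at 0, a fall on this scale is a fall relative to the other clones of the array. Every comparison was therefore also computed with each array shifted after loess so that the 4 control clones (L17, S14, S16 and S3 in the files) have a mean log2 ratio of 0, called the control scale. The labels describe these ribosomal protein clones as unaffected by treatment. In the authors' ratios the median of these 4 clones lies between 0.99 and 1.00 on every array, so these clones set that scale. The design text names another set (S14, S16, L23 and L15), so which genes 2 of the 4 clones carry is open.

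A clone was taken as well above background in a channel when its mean signal exceeded the local background by 2 background SD. Where a clone did not reach this in the hydrated channel of either array of a comparison, its fold is given as a lower bound. The bound sets the clone's mean treated level against the level at that limit in the hydrated channel, on the same normalized scale, and no fold is given where the bound is below 1 or where both channels fell short. Fitted log2 values of such clones are not bounds. Array data have no counting depth, and their number limits the precision.

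Clones to name were fixed by rule before the data were examined, as were the gene lists and the alternatives below unless stated. For each comparison with hydrated tissue the rule took the 10 annotated clones with the largest rise and the 10 with the largest fall among those called and moving the same way on both arrays, 1 clone per annotated gene. It added up to 2 clones with no annotation in each direction, up to 4 members of each list, and every control clone. For each difference it took 5 in each direction. Of list members, those of 8 lists are given by counts alone.

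The 15 lists were search patterns on the annotation text, for late embryogenesis abundant (LEA) and desiccation proteins, early light-inducible proteins, ribosomal proteins, translation factors, antioxidant and redox enzymes, chaperones, photosynthesis, membrane transport, signalling, transcription and RNA binding, protein degradation, cell wall and carbohydrate, lipid metabolism, cytoskeleton and primary metabolism. Lists with at least 3 clones were tested with camera of limma, with a preset inter-gene correlation of 0.01 and with a correlation estimated from the data, over the annotated clones. On the control scale only the preset correlation was used. The fry test of limma was also run but is not reported, since it tests a list against no change and not against other clones. The LEA list without its 7 Tr clones was tested outside the plan.

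Alternatives covered the background (none, or plain subtraction), the normalization (median centring, print-tip loess, the control scale, and dye-swap normalization, which removes only the trend shared by both dye orientations), removal of dim clones, a fit with no dye term, a fit on the 4 arrays of 1 RNA fraction, spots kept separate, array weights, the authors' ratios, another reading of the label of slide 85, and each array left out in turn. Chosen after seeing the data were the signal median in place of the mean, removal of spots with a flag above 0, and the control shift with no loess. The method was tested on simulated data in which 200 of 768 clones were changed. As many were raised as lowered, and the noise between arrays was set equal in all groups. The test therefore does not cover a shift of most clones in the same direction, or noise that differs between groups. Of clones changed by a log2 of 1, between 68 and 86% were recovered in the comparisons with hydrated tissue, and of clones changed by 2 between 98 and 99%, none with the wrong sign, while false calls made up between 2.31 and 8.59% of calls over the 8 results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sequence accessions of the clones were not used here, and no spots were removed by hand.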

Results

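The moss Tortula ruralis, also named Syntrichia ruralis, survives loss of nearly all its cell water and resumes metabolism on rewetting. The arrays compared its transcripts in dried or rehydrated gametophytes with those in hydrated ones, in total RNA and in polysomal RNA. Polysomal RNA is the fraction prepared as bound to several ribosomes. Translation itself was not measured. Slow-dried plants had lost water over 24 h at a relative humidity of 66% and 20 °C, rapid-dried plants had been rewetted for 2 h, and plants were kept hydrated for 48 h beforehand, per the labels. There were 2 arrays for each of the 4 comparisons with hydrated tissue. Every array held 768 clones in 3 spots each, of which 559 carried no annotation and 209 did. The clones came from a subtracted cDNA library, so they are no random sample of the moss's genes.

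Between 82.0 and 98.4% of clones lay well above background in the treated channel of an array. In the hydrated channel the share ran from 66.5 to 94.8%, except on replicate 1 of rapid-dried rehydrated total RNA, where it was 38.7%. Across the 768 clones, which are not independent replicates, the log2 ratios of the 2 arrays correlated at r = 0.87 for slow-dried total RNA, 0.78 for rapid-dried rehydrated total RNA, 0.92 for slow-dried polysomal RNA and 0.93 for rapid-dried rehydrated polysomal RNA. The title of 1 array of the last pair (slide 85) says slow-dried, while its source name and protocol say rapid-dried and rehydrated. It was used as the latter, since its log2 ratios correlated at 0.93 with the other array of that treatment and at 0.73 and 0.74 with the slow-dried polysomal arrays.

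Log2 ratios below are of treated over hydrated tissue relative to the typical clone, with n = 2 arrays per comparison. They are given with the standard error of the limma fit, which pools the spread over all arrays. A clone therefore has the same standard error in all 4 comparisons with hydrated tissue. That error does not measure the spread between the 2 arrays of a comparison. Transcripts of the 4 ribosomal protein control clones lay below the typical clone in all 4 comparisons, so the scale matters for every fall. The median clone stood above the control clones by a log2 of 1.53 in slow-dried total RNA, 1.18 in rapid-dried rehydrated total RNA, 1.44 in slow-dried polysomal RNA and 1.04 in rapid-dried rehydrated polysomal RNA. On the control scale the calls were therefore nearly all upward, and the authors' own ratios are on such a scale, with array medians from 2.02 to 4.81. All clones called higher than in hydrated tissue were also called higher on the control scale, which does not hold for the differences between comparisons.

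**Figure D1:**
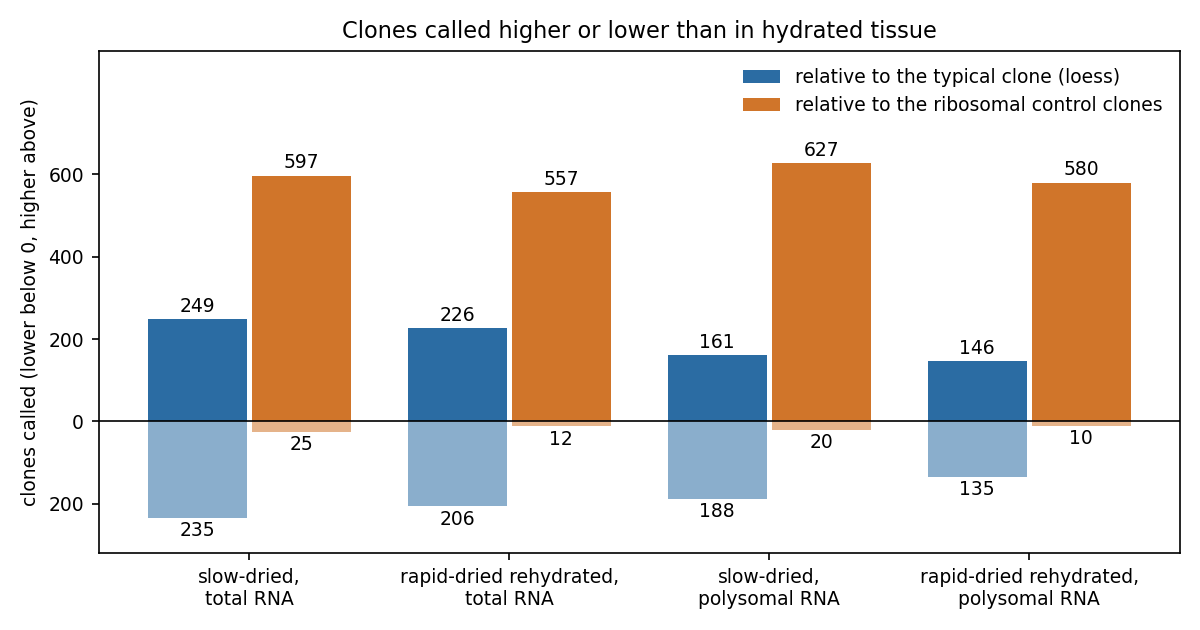
Number of clones called higher (above 0) or lower (below 0, paler) than in hydrated tissue at an adjusted p under 0.05, by treatment and RNA fraction, relative to the typical clone or to the ribosomal control clones. In slow-dried total RNA 235 clones were lower than the typical clone's level but 25 were lower than the controls.

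**Figure D2:**
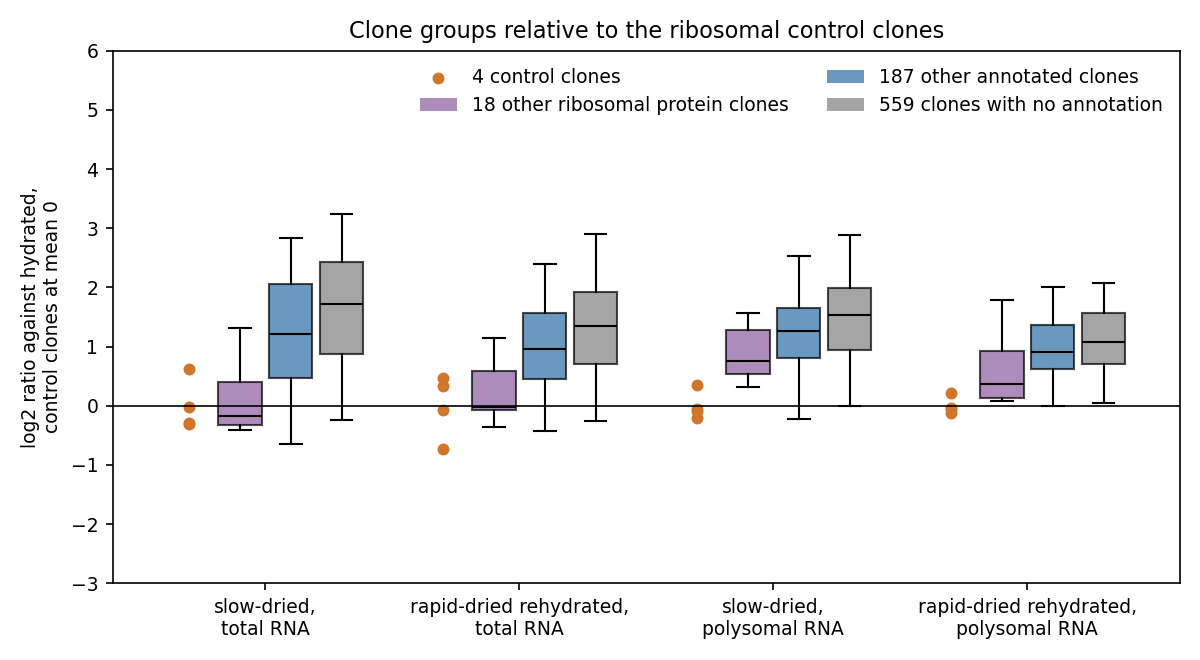
Log2 ratio of treated over hydrated signal (vertical) relative to the mean of the 4 control clones, as boxes of medians and quartiles over clones with whiskers at percentiles 5 and 95, for 18 other ribosomal protein clones, 187 other annotated clones and 559 with no annotation, and as points for the controls. The other ribosomal protein clones lay near the controls in total RNA (medians -0.18 and -0.026) and above them in slow-dried (0.76) and rapid-dried rehydrated polysomal RNA (0.37).

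What slow drying did to the transcript pool was asked first in total RNA. Catalase, which breaks down hydrogen peroxide, was 4.41-fold higher (log2 2.14 ± 0.18, adjusted p = 0.000222), and ELIPA and ELIPb, early light-inducible proteins of the thylakoid, rose by 1.46 and 2.02. The dehydrin LTI30/XERO2, of the LEA proteins that accumulate in drying cells, rose by 1.49 ± 0.18. Chloroplast carbonic anhydrase, which interconverts carbon dioxide and bicarbonate, fell by 3.11 (SE 0.18), photosystem I subunit III, which docks plastocyanin, by 3.00, and a light-harvesting chlorophyll a/b-binding protein by 3.09, and all 3 were also lower on the control scale (-1.63, -1.51 and -1.60).

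Among the other annotated clones with the largest rises in slow-dried total RNA were a putative abscisic acid-responsive protein related to fip1 (USD-454, 1.63 ± 0.31), an msf1-like protein (USD-258, 1.48 ± 0.38), a second cDNA of the rehydrin Tr-288 (USD-231, 1.39 ± 0.15) and an sl15-like PQ-loop protein (USD-53, 1.37 ± 0.34). Toc125, of the chloroplast import machinery, was at least 4.05-fold higher and glycolate oxidase, a photorespiratory enzyme, at least 2.54-fold, since neither was well above background in the hydrated channel. Of clones with no annotation, USD-6 rose by 3.01 ± 0.22 and USD-22 was at least 4.71-fold higher. The other large falls, all also called on the control scale, were in a 16 kDa membrane protein (USD-275, -3.74 ± 0.17), microsomal glutathione S-transferase 3 (-3.09 ± 0.16), the rehydrin Tr-416 (-3.06 ± 0.18), a hypothetical endonuclease/exonuclease/phosphatase protein (USD-119, -3.04 ± 0.17), SnRK1-interacting protein 1 (-2.36 ± 0.16), a mob1/phocein protein (-2.25 ± 0.18) and glyoxalase I, which detoxifies methylglyoxal (-2.14 ± 0.24). USD-72 and USD-762, which have no annotation, fell by 3.88 and 3.77, also on the control scale (-2.40 and -2.28).

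By list, 20 of 22 ribosomal protein clones were lower in slow-dried total RNA and 0 higher, among them L35 (-2.05 ± 0.16) and L18 (-1.87 ± 0.15), but on the control scale 0 were lower and 5 higher. The list's adjusted p in camera was 0.000391, and the adjusted p = 0.701 with an estimated correlation. The list includes the 4 control clones that set the control scale. Without them 16 of 18 were lower and 0 higher, against 0 and 4 on the control scale. Their camera unadjusted p was 0.000195, and 0.207 with an estimated correlation. Of 13 LEA and desiccation clones 5 rose and 4 fell, and of 12 antioxidant and redox clones 5 rose, with dehydroascorbate reductase (1.15 ± 0.16) beside catalase, and 3 fell. Against the controls 10 LEA clones were higher and 1 lower, and 9 antioxidant clones higher and 2 lower. In both of these lists the median was above 0 and the mean below it, and adjusted over the list alone 4 antioxidant clones fell. The 4 LEA falls were all in Tr clones, of which the labels name Tr-217, Tr-416 and Tr-421 as controls from earlier northern blots, and of the 6 other LEA clones 4 rose and 0 fell (median 1.05, camera unadjusted p = 0.0082, and 0.0719 with an estimated correlation). Elongation factor 1 alpha (-1.37), an eIF4-gamma/eIF5 domain protein (-0.72) and Hsp90 (-1.17) were lower than the typical clone but above the controls on the control scale (0.12, 0.76 and 0.31), and Hsp70 (-1.51) stood at -0.025 on that scale and above 0 in the authors' ratios. In all, limma called 249 clones higher and 235 lower of 768 against 597 and 25 on the control scale. Dye-swap normalization gave 539 and 49, and the authors' ratios 477 and 19.

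The same question was asked of plants dried rapidly and rewetted for 2 h, in total RNA. The flavoprotein subunit of succinate dehydrogenase, a mitochondrial enzyme, was 4.45-fold higher (log2 2.15 ± 0.16, adjusted p = 0.00046), and trehalase, which splits trehalose into glucose, rose by 1.51 ± 0.27. Senescence-associated protein 12 (USD-38, 2.10 ± 0.41), a putative MAP kinase-activating protein (USD-469, 1.99 ± 0.18) and the fip1-related clone (USD-454, 1.93 ± 0.31) also rose, and catalase was at least 3.12-fold higher. The largest fall was in GLU2, ferredoxin-dependent glutamate synthase, which assimilates ammonium (-2.25 ± 0.19, and -1.06 on the control scale).

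Transcripts of DBF1, an AP2-domain transcription factor, were at least 1.04-fold higher in this comparison. Toc125 and a glyceraldehyde-3-phosphate dehydrogenase (USD-566) were called higher, but their bounds were below 1, and a putative ethanolamine kinase (USD-354) was called with neither channel well above background. USD-22 and USD-255, with no annotation, were at least 7.81-fold and 5.29-fold higher. Lower on both scales were a cyclohexanone monooxygenase (-2.02 ± 0.14), a vacuolar aspartic proteinase (-1.97 ± 0.19), Tr-421 (-1.96 ± 0.14), USD-119 (-1.96 ± 0.17), ribosomal protein S3 (-1.92 ± 0.17), an ABC transporter (USD-745, -1.80 ± 0.14), and the clones with no annotation USD-288 (-1.97 ± 0.27) and USD-195 (-1.89 ± 0.14). S3 is itself a control clone that helps set the control scale. SnRK1-interacting protein 1 (-1.78 ± 0.16) was lower but not past the threshold on the control scale. Glucose-6-phosphate dehydrogenase (-1.73 ± 0.15) and ribosomal protein L18 (-1.70 ± 0.15) were lower, but turned just above 0 with dye-swap normalization and in the authors' ratios.

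Of the 22 ribosomal protein clones 17 were lower after rehydration and 1 higher, against 1 and 5 on the control scale. Adjusted over the list alone 18 were lower. The camera adjusted p was 0.0034, and the adjusted p = 0.916 with an estimated correlation. Without the 4 control clones 13 of 18 were lower and 1 higher, against 0 and 5 on the control scale. Their camera unadjusted p was 0.0016, and 0.269 with an estimated correlation. All 3 photosynthesis clones were lower than the typical clone (carbonic anhydrase -1.49, the chlorophyll a/b-binding protein -1.25 and photosystem I subunit III -1.01) but none passed on the control scale, where they stood at -0.31, -0.068 and 0.18. Of 13 LEA and desiccation clones 4 rose, among them USD-231 (1.06 ± 0.15) and the Lea protein USD-161 (1.05 ± 0.17), and 4 fell, all of them Tr clones and among them Tr-416, which stood above 0 with dye-swap normalization and in the authors' ratios. Against the controls 9 LEA clones were higher and 1 lower. Of the 6 LEA clones that are no Tr clones 4 rose and 0 fell (camera unadjusted p = 0.0124, and 0.0816 with an estimated correlation). ELIPA rose by 0.61, while ELIPb, at 0.12, did not pass. Of 12 antioxidant and redox clones 3 rose and 3 fell relative to the typical clone, against 9 and 0 on the control scale. The falls were in microsomal glutathione S-transferase 3 (-1.05), glyoxalase I (-1.36) and the moss aldehyde dehydrogenase Aldh21A1 (-0.68), but each turned above 0 on the dye-swap scale. Of the translation factors, elongation factor 1 alpha (-1.16) and the eIF4-gamma/eIF5 domain protein (-1.24) were lower but also turned above 0 on that scale. The chaperones Hsp90 (-0.75) and a Clp protease regulator (-0.26) did not pass, with a channel not well above background. In total limma called 226 clones higher and 206 lower, against 557 and 12 on the control scale, 604 and 3 with dye-swap normalization and 536 and 1 in the authors' ratios.

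In polysomal RNA of slow-dried plants the question was how the polysomal pool differed from that of hydrated plants. The 3 photosynthesis clones were lower in it on both scales. Carbonic anhydrase was 14.5-fold lower (log2 -3.86 ± 0.18, adjusted p = 0.000223), photosystem I subunit III -3.25 ± 0.21 and the chlorophyll a/b-binding protein -2.93 ± 0.39. Higher in it than the typical clone were glycolate oxidase (1.60 ± 0.34), the vesicle-fusion protein VAMP714 (1.44 ± 0.19), a serine decarboxylase, which makes ethanolamine (1.33 ± 0.18), the dehydrin LTI30/XERO2 (1.29 ± 0.18) and catalase (1.21 ± 0.18).

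Further rises in slow-dried polysomal RNA were in a hypothetical protein (USD-450, 2.04 ± 0.17), an alpha/beta-fold hydrolase (USD-117, 1.61 ± 0.13), a grim19-like protein, a homologue of which belongs to mitochondrial complex I (1.18 ± 0.15), Tr-217 (1.17 ± 0.19), a proline-rich protein (USD-569, 1.17 ± 0.14), and, with no annotation, USD-34 (2.14 ± 0.42) and USD-560 (1.93 ± 0.27). The 16 kDa membrane protein (-3.35 ± 0.17), microsomal glutathione S-transferase 3 (-2.83 ± 0.16), a chitinase (USD-667, -2.16 ± 0.18), a soluble epoxide hydrolase (USD-766, -2.13 ± 0.16), Tr-416 (-2.07 ± 0.18), and, with no annotation, USD-188 (-3.09 ± 0.36) and USD-390 (-2.66 ± 0.33) were lower on both scales. The peptidyl-prolyl isomerase rof1 (-2.03 ± 0.21) and a protein phosphatase 2C (-1.79 ± 0.13) were lower but not past the threshold on the control scale.

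Of the 22 ribosomal protein clones 14 were lower in slow-dried polysomal RNA and 1 higher, against 0 and 10 on the control scale. The list's camera adjusted p was 0.068, and the adjusted p = 0.881 with an estimated correlation. Without the 4 control clones 10 of 18 were lower and 1 higher, against 0 and 10 on the control scale. Their camera unadjusted p was 0.0535, and 0.472 with an estimated correlation. The 3 photosynthesis clones all fell on both scales. Relative to the typical clone the list's camera adjusted p was 0.068, and the adjusted p = 0.881 with the estimated correlation of 0.849. On the control scale the camera adjusted p was 3.89e-10 with the preset correlation, and an estimated one was not tried there. Of 13 LEA and desiccation clones 3 rose and 5 fell (2 and 1 of 6 without the Tr clones), against 10 and 1 on the control scale, and of those that fell Tr-421 (-1.01) stood above 0 on the control scale (0.40). ELIPA rose by 0.56, and ELIPb (0.35) did not pass. Of 12 antioxidant and redox clones 1, catalase, rose and 4 fell, against 8 and 1 on the control scale, among the falls stromal ascorbate peroxidase, which removes hydrogen peroxide in the chloroplast (-1.42 ± 0.21), and mitochondrial aldehyde dehydrogenase (-0.92), which was above the controls on the control scale (0.49). Of the chaperones Hsp70 (-1.30) and Hsp90 (-1.43) were lower, at 0.11 and -0.023 on the control scale, and of the translation factors the eIF4-gamma/eIF5 domain protein fell (-1.48) and elongation factor 1 alpha (-0.33) did not pass. For this comparison limma called 161 clones higher and 188 lower, against 627 and 20 on the control scale, 559 and 38 with dye-swap normalization and 412 and 20 in the authors' ratios. Left with 1 array, the comparison had 129 calls without replicate 1 and 137 without replicate 2.

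For polysomal RNA of rapid-dried rehydrated plants the same question was asked after 2 h of rehydration. The serine decarboxylase (1.53 ± 0.18, adjusted p = 0.0041), glycolate oxidase (1.16 ± 0.34), trehalase (1.06 ± 0.27), an oligopeptide transporter annotated for iron (USD-408, 1.18 ± 0.27), ERD4, an early response to dehydration protein (1.10 ± 0.17), and the Lea protein USD-161 (0.98 ± 0.17) were higher than in hydrated polysomal RNA. Carbonic anhydrase was 5.58-fold lower (log2 -2.48 ± 0.18), the 16 kDa membrane protein fell by 2.47, photosystem I subunit III by 2.36, the epoxide hydrolase USD-766 by 1.98 and stromal ascorbate peroxidase by 1.79, all also lower on the control scale.

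USD-450 (1.83 ± 0.17), a hypothetical cell surface protein (USD-387, 1.08 ± 0.16), a protein like Arabidopsis At5g01750 (USD-204, 0.98 ± 0.13), the hydrolase USD-117 (0.97 ± 0.13), and, with no annotation, USD-676 (1.82 ± 0.37) and USD-389 (1.53 ± 0.17) also rose. USD-319 (-2.23 ± 0.18) and USD-390 (-0.95 on the control scale), with no annotation, were lower on both scales. The chlorophyll a/b-binding protein (-1.69 ± 0.39), glucose-6-phosphate dehydrogenase (-1.63 ± 0.15), the eIF4-gamma/eIF5 domain protein (-1.22 ± 0.17) and the control clones S16 (-1.17 ± 0.30) and L17 (-1.10 ± 0.14) were lower but not past the threshold on the control scale.

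Of the 22 ribosomal protein clones 13 were lower and 2 higher in this comparison, against 0 and 7 on the control scale, with L18 at -0.98 and at 0.076 on the control scale. Adjusted over the list alone 14 were lower. The camera adjusted p was 0.0326, and the adjusted p = 0.98 with an estimated correlation. Without the 4 control clones 9 of 18 were lower and 2 higher, against 0 and 7 on the control scale. Their camera unadjusted p was 0.0242, against 0.0025 with them, and 0.408 with an estimated correlation. All 3 photosynthesis clones fell, and 2 of them did on the control scale. Relative to the typical clone the list's camera adjusted p was 0.0985, and the adjusted p = 0.98 with an estimated correlation. On the control scale the camera adjusted p was 2.04e-08 with the preset correlation, and an estimated one was not tried there. Of 13 LEA and desiccation clones 1 rose and 2 fell (1 and 1 of 6 without the Tr clones), against 9 and 0 on the control scale, among the falls the Lea protein USD-165 (-0.57), which was above the controls on the control scale (0.48). Neither ELIPA (-0.15) nor ELIPb (-0.52) passed. Of 12 antioxidant and redox clones catalase rose by 0.69 and 4 fell, against 8 and 1 on the control scale, and of the falls microsomal glutathione S-transferase 3 (-1.02) and mitochondrial aldehyde dehydrogenase (-0.80) were above the controls on the control scale (0.031 and 0.25). Elongation factor 1 alpha (-0.44) was lower than the typical clone and higher on the control scale (0.61), and the chaperones Hsp90 (-0.74) and the Clp regulator (0.12) did not pass. The fit called 146 clones higher and 135 lower, against 580 and 10 on the control scale, 158 and 125 with dye-swap normalization and 342 and 6 in the authors' ratios. With either 1 of its 2 arrays left out limma called 0 clones, with 180 and 185 at an unadjusted p under 0.05, and with slide 85 read as slow-dried it called 6.

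**Figure D3:**
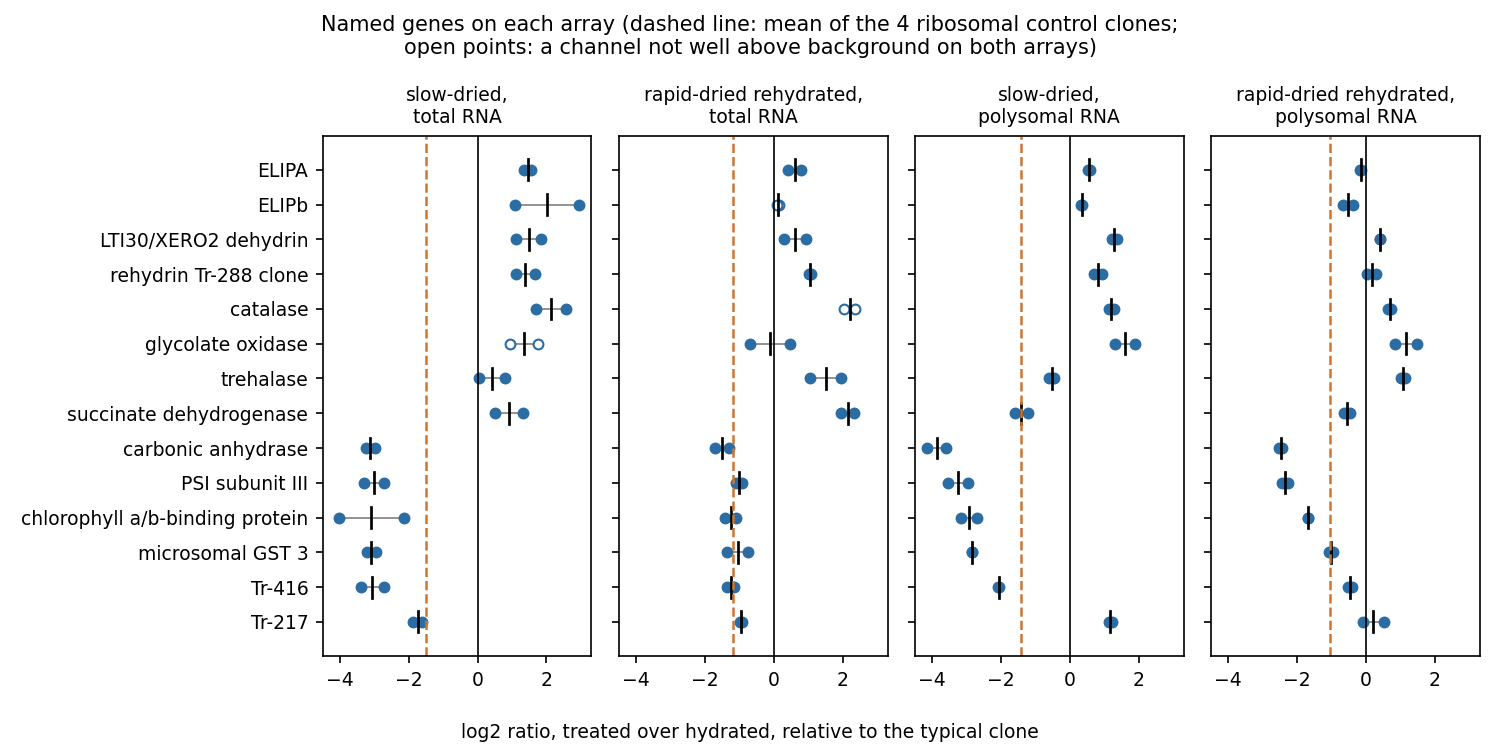
Log2 ratio of treated over hydrated signal relative to the typical clone for 14 named clones in the 4 comparisons, 1 point per array (2 arrays each), with the mean as a black bar and open points where a channel was not well above background on both arrays. The dashed line marks the mean of the control clones, so points between it and 0 are lower than the typical clone but higher than the controls; the mean of carbonic anhydrase lies left of it in all 4 panels.

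The other lists were described by counts alone, and no camera test of them passed in any of the 4 comparisons, with adjusted p of at least 0.365 in slow-dried total RNA. In the order slow-dried total, rapid-dried rehydrated total, slow-dried polysomal and rapid-dried rehydrated polysomal RNA, the higher and lower clones of the 13 signalling clones numbered 1 and 5, 3 and 4, 1 and 3, and 0 and 3. Of 10 membrane transport clones they numbered 1 and 3, 0 and 3, 0 and 2, and 1 and 2, and of 9 protein degradation clones 2 and 5, 2 and 4, 0 and 5, and 0 and 3. Of the 6 clones matched by the cell wall and carbohydrate pattern 0 rose in any comparison and 4, 3, 2 and 1 fell. That pattern searched for trehalose and so missed the trehalase clones. Of these USD-578 rose in rapid-dried rehydrated total (1.51) and polysomal RNA (1.06). Of 29 primary metabolism clones 5, 5, 3 and 4 rose and 13, 12, 8 and 6 fell. Of 6 lipid clones 1 rose and 2 fell, 0 and 2, 1 and 0, and 1 and 1, and of 4 transcription and RNA-binding clones 1 and 0, 1 and 1, 0 and 1, and 0 and 0. The 3 translation factors had 0 and 2, 1 and 2, 0 and 1, and 0 and 2, and the 1 cytoskeleton clone passed in none. The 3 chaperones had 0 and 2, 0 and 0, 0 and 2, and 0 and 0. The isomerase rof1, which fell in slow-dried polysomal RNA, was counted under primary metabolism, since the chaperone pattern missed the spelling of its annotation. Median and mean differed in sign for the LEA and transcription lists in rapid-dried rehydrated total RNA, for the antioxidant, cell wall, lipid and primary metabolism lists in slow-dried polysomal RNA, and for the LEA, chaperone and membrane transport lists in rapid-dried rehydrated polysomal RNA. The camera direction was upward with median and mean below 0 for the antioxidant and primary metabolism lists in rapid-dried rehydrated total RNA, for the LEA, membrane transport and transcription lists in slow-dried polysomal RNA, and for the primary metabolism and transcription lists in rapid-dried rehydrated polysomal RNA. On the control scale each list counted in this paragraph had 0 or 1 lower clones in each comparison and more higher ones. Adjusted over the list alone, counts in these 4 comparisons differed by at most 1 from those given, for every list.

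The rehydrin control clones had been chosen from earlier northern blots, per the labels. L17, S14, S16 and S3 were lower than the typical clone in all 4 comparisons, with log2 ratios from -1.92 (S3, rapid-dried rehydrated total RNA) to -0.71 (L17, the same comparison), which on the control scale became -0.73 and 0.47, since that scale is centred on them. Tr-155, Tr-403 and Tr-421, which the labels list as up-regulated, did not share a direction. Tr-155 (0.45, 0.41, -0.14 and 0.41 in the order above) and Tr-403 (0.14, 0.22, -0.075 and 0.12) passed in none, though both were higher in all 4 on the control scale, and Tr-403 was in neither channel well above background in rapid-dried rehydrated total RNA. Tr-421 was lower than the typical clone in all 4 (-1.70, -1.96, -1.01 and -0.54), and stood at -0.21, -0.78, 0.40 and 0.51 on the control scale. Tr-416, listed as down-regulated, fell on both scales in slow-dried total and polysomal RNA. Tr-217, listed likewise, was at -1.74 ± 0.19 in slow-dried total RNA, where it did not pass on the control scale (-0.25), and at 1.17 ± 0.19 in the polysomal fraction. The calmodulin-domain protein kinase clone Tr-cpk, listed as neutral, was at -0.38, -0.97, -1.49 and 0.037, and was called lower in rapid-dried rehydrated total RNA and slow-dried polysomal RNA, although above the controls in the former (0.21). Tr-418 was lower than the typical clone in 3 comparisons (-0.45, -0.68 and -0.55) and above the controls in each (1.04, 0.51 and 0.86).

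Slow-dried plants were also set against rapid-dried rehydrated plants, by the difference of their log2 ratios against hydrated tissue. These differ in the rate of drying and in rehydration at once, so the contrast cannot assign a response to either. It is called slow drying against rehydration below. In total RNA, ELIPb stood higher after slow drying by a log2 of 1.90 ± 0.47, and so did a spherulin-1B precursor (1.28 ± 0.20), lipoxygenase-1, which oxidises unsaturated fatty acids (1.25 ± 0.18), dehydroascorbate reductase (USD-154, 1.21 ± 0.26), a glyoxalase family protein (USD-102, 1.12 ± 0.24) and, with no annotation, USD-125 (2.39 ± 0.25) and USD-6 (2.16 ± 0.31). ELIPb, USD-102 and USD-6 were each not well above background in the hydrated channel of 1 of the comparisons. Lower after slow drying were the 16 kDa membrane protein (-2.28 ± 0.24), microsomal glutathione S-transferase 3 (-2.04 ± 0.22), photosystem I subunit III (-1.99 ± 0.30), thioredoxin H (-1.96 ± 0.43), Tr-416 (-1.80 ± 0.25) and, with no annotation, USD-698 (-3.33 ± 0.20) and USD-762 (-2.88 ± 0.32), all with the same direction and past the threshold on the control scale. Of the lists, both early light-inducible clones were higher (1 on the control scale) and 2 of 3 photosynthesis clones lower after slow drying, or 3 on the control scale and adjusted over the list alone, where 2 protein degradation clones were lower against 1 over all clones and 0 on the control scale. Of 22 ribosomal protein clones 0 were higher and 5 lower, against 1 and 0 on the control scale. Their camera adjusted p was 0.0978, and the adjusted p = 0.874 with an estimated correlation. Of 29 primary metabolism clones 1 was higher and 6 lower, against 1 and 2 on the control scale. The camera adjusted p of the photosynthesis list relative to the typical clone was 0.114, and the adjusted p = 0.874 with an estimated correlation. On the control scale it was 0.0031 with the preset correlation alone.

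Across the clones limma called 49 higher and 87 lower after slow drying in total RNA, against 56 and 33 on the control scale. Dye-swap normalization gave 44 and 155, and the authors' ratios gave 0 (152 at an unadjusted p under 0.05). A fit on the total RNA arrays alone called 19 higher and 40 lower, and array weights 16 and 26. The count was 60 without replicate 2 of slow-dried total RNA, 62 without either array of rapid-dried rehydrated polysomal RNA and 80 without either array of slow-dried polysomal RNA, since the comparisons share 1 estimate of spread.

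In polysomal RNA, microsomal glutathione S-transferase 3 (-1.81 ± 0.22), Tr-416 (-1.62 ± 0.25), Tr-cpk (-1.53 ± 0.23), the protein phosphatase 2C (-1.44 ± 0.18), carbonic anhydrase (-1.38 ± 0.26) and, with no annotation, USD-698 (-2.10 ± 0.20) and USD-389 (-2.04 ± 0.24) stood lower after slow drying than after rehydration. USD-389 was not well above background in slow-dried polysomal RNA. USD-324 (1.41 ± 0.26) and USD-131 (1.07 ± 0.18), with no annotation, were the 2 clones higher after slow drying. Limma called 2 clones higher and 28 lower, but 0 on the control scale, where 172 had an unadjusted p under 0.05. Without any 1 of the 4 polysomal arrays limma also called 0, with between 64 and 104 at an unadjusted p under 0.05, while a fit on the polysomal arrays alone called 167 higher and 173 lower, and dye-swap normalization 571 and 8. Spots kept separate gave 66 and 86, array weights 112 and 127, and 47 were called without either array of slow-dried total RNA. Of the LEA and desiccation list 0 clones were higher and 1 lower over all clones, and 2 and 1 adjusted over the list alone, which also called 1 early light-inducible clone higher, against 0, and 2 photosynthesis clones lower, against 1.

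No array compared the 2 fractions directly, so the log2 ratio against hydrated tissue in polysomal RNA was set against that in total RNA. Higher and lower here refer to this difference of ratios, not to the level in either fraction. In slow-dried plants the ratio of Tr-217 was higher in polysomal RNA by a log2 of 2.91 ± 0.26 (adjusted p = 0.0015), ribosomal protein L38 (USD-47) by 2.69 ± 0.25, USD-119 by 3.54 ± 0.24, USD-450 by 3.06 ± 0.25, the hydrolase USD-117 by 2.52 ± 0.18, and the clones with no annotation USD-72 by 3.42 ± 0.30 and USD-292 by 3.10 ± 0.81. Toc125 (-2.43 ± 0.48), a putative protease (USD-279, -2.38 ± 0.21), succinate dehydrogenase (-2.32 ± 0.22), Tr-288 (-2.11 ± 0.43), the protein phosphatase 2C (-2.06 ± 0.18) and, with no annotation, USD-237 (-3.08 ± 0.42) and USD-319 (-2.90 ± 0.25) stood lower. All of these kept their direction and passed on the control scale. A second clone of L38, USD-194, lay the other way but did not pass (-0.98, adjusted p = 0.106). Toc125 was not well above background in hydrated total RNA, nor Tr-288 in treated polysomal RNA. USD-231, which carries the name of Tr-288, was called higher than in hydrated tissue in both fractions (1.39 in total and 0.83 in polysomal RNA). Of 22 ribosomal protein clones 10 had a higher ratio in polysomal than in total RNA and 0 a lower one, or 12 adjusted over the list alone, and on the control scale 8 did. The camera adjusted p was 0.0225, and the adjusted p = 0.837 with an estimated correlation. Both early light-inducible clones had a lower ratio in polysomal RNA, and of 12 antioxidant clones 4 did and 0 had a higher one. Only 1 early light-inducible clone was lower on the control scale, where 2 antioxidant clones were lower and 1 higher. Adjusted over the list alone 5 antioxidant clones were lower and 2 higher. That adjustment also took the LEA list from 3 higher and 3 lower to 3 and 4, translation factors from 1 and 0 to 1 and 1, signalling from 2 and 2 to 3 and 2, cell wall from 2 and 0 to 3 and 0, and lipid metabolism from 1 and 0 to 2 and 2, while on the control scale these 5 lists had 1 and 1, 0 and 0, 1 and 3, 2 and 0, and 1 and 0.

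For slow drying limma called the ratio of 106 clones higher and of 119 lower in polysomal than in total RNA, against 71 and 75 on the control scale. The authors' ratios gave 12 and 13. The count fell to 62 and 75 without 1 slow-dried polysomal array, 111 without replicate 2 of slow-dried total RNA, and 130 without 1 array of rapid-dried rehydrated polysomal RNA.

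In rapid-dried rehydrated plants USD-119 (2.46 ± 0.24), ribosomal protein L38 (USD-47, 2.10 ± 0.25), GLU2 (1.97 ± 0.27), a polyamine oxidase, which degrades polyamines (1.71 ± 0.47), and, with no annotation, USD-184 (2.82 ± 0.41) and USD-331 (2.31 ± 0.23) had a higher ratio in polysomal than in total RNA. The ABC transporter USD-745 did too (1.73 ± 0.20), but lay just below 0 with dye-swap normalization. Succinate dehydrogenase (-2.70 ± 0.22), the MAP kinase-activating protein USD-469 (-1.78 ± 0.26), the fip1-related clone USD-454 (-1.55 ± 0.43), catalase (-1.52 ± 0.25), USD-285, a protein like At5g01750 (-1.37 ± 0.23) and, with no annotation, USD-255 (-3.63 ± 0.22) and USD-237 (-3.36 ± 0.42) stood lower. USD-469, catalase, USD-255 and USD-237 were each not well above background in the hydrated channel of 1 of the comparisons. Of 22 ribosomal protein clones 7 stood higher and 1 lower, against 1 and 0 on the control scale, and the camera adjusted p was 0.573. On both scales 0 of 12 antioxidant clones stood higher and 3 lower, and 0 and 2 of 3 photosynthesis clones. The camera adjusted p of these lists was 0.650 and 0.573. Adjusted over each list alone, the LEA list went from 2 higher and 2 lower to 3 and 2, signalling from 3 and 2 to 4 and 3, and protein degradation from 3 and 1 to 3 and 2, while on the control scale they had 1 and 2, 1 and 2, and 0 and 1. Limma called 111 clones higher and 119 lower, against 43 and 101 on the control scale and 5 and 608 with dye-swap normalization. The authors' ratios gave 0, with 223 at an unadjusted p under 0.05. Without either array of rapid-dried rehydrated polysomal RNA 2 were called, and with slide 85 read as slow-dried 16. The fractions came from separate RNA preparations and slides, so fraction and hybridisation batch cannot be told apart in either contrast.

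**Figure D4:**
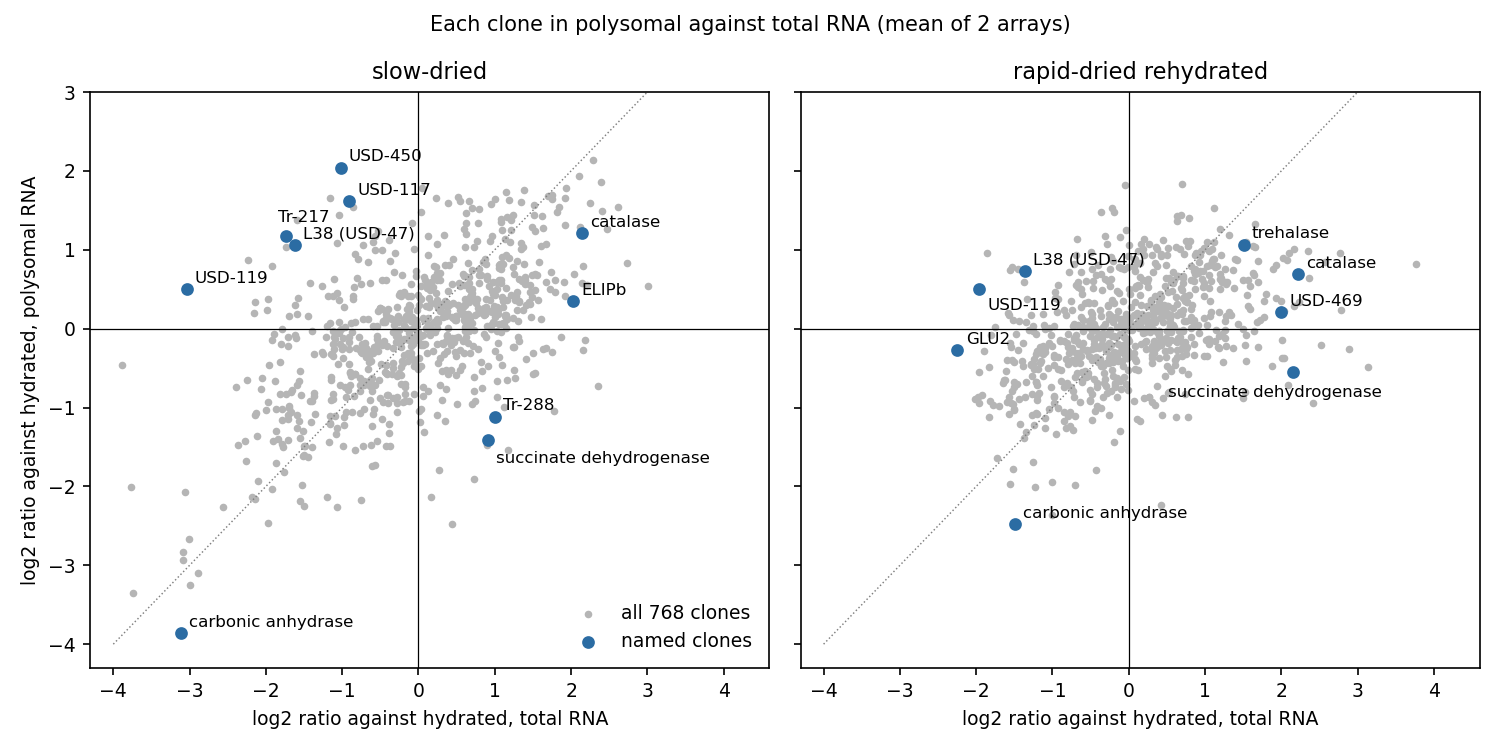
Log2 ratio against hydrated tissue in polysomal RNA (vertical) and in total RNA (horizontal) for the 768 clones, slow-dried at left and rapid-dried rehydrated at right, relative to the typical clone and as means of 2 arrays. Clones far from the dotted diagonal and called different between fractions include Tr-217 (left panel) and ribosomal protein L38 (USD-47) at upper left. Succinate dehydrogenase at lower right is another (not below the controls in polysomal RNA on the control scale). In all 225 clones were called different after slow drying and 230 after rehydration, so most points off the diagonal were not.

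The responses of slow-dried and of rapid-dried rehydrated plants overlapped. In total RNA 162 clones were higher and 155 lower in both treatments, where 73.3 and 63.0 would be shared by chance, and in polysomal RNA 85 and 109, where 30.6 and 33.0 would. The log2 ratios correlated across clones at 0.73 in total and 0.75 in polysomal RNA. The labels do not say whether the hydrated RNA was shared between treatments. A simulation of no change with all noise of the hydrated channel shared gave correlations of 0.50 in both, and a covariance of 0.023 against 0.77 in total and 0.42 in polysomal RNA. The 0.50 follows from giving both channels equal noise. That noise was sized from the spread between arrays of the same comparison, so an error common to both arrays is not in it. The simulation thus sets no upper bound on the effect of shared hydrated RNA. Across all 4 comparisons 45 clones were higher throughout, among them catalase, the serine decarboxylase and 41 with no annotation, and 66 were lower throughout, of which 0 were called lower in all 4 on the control scale. Without either array of rapid-dried rehydrated polysomal RNA that comparison has 0 calls, so neither these counts nor the shared calls in polysomal RNA would remain.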

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

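The tests of the other ribosomal protein clones and of the identity of slide 85 were chosen only after the result was seen. Several transcripts responded differently to the treatments or between the RNA fractions, by limma tests of the difference itself over n = 2 arrays per group. In total RNA 136 clones differed between slow drying and rehydration after rapid drying, with ELIPb (USD-305) higher after slow drying by a log2 of 1.90 and the 16 kDa membrane protein (USD-275) at -2.28. The count was 60 without replicate 2 of slow-dried total RNA, 62 without either array of rapid-dried rehydrated polysomal RNA and 80 without either array of slow-dried polysomal RNA. In polysomal RNA 30 clones differed, with microsomal glutathione S-transferase 3 (USD-460) at -1.81. Both counts rest on 1 estimate of spread shared by the fractions. Fitted on the arrays of 1 fraction alone, 59 clones differed in total and 340 in polysomal RNA, and array weights gave 42 and 239. The counts therefore do not rank the fractions. These 30 calls ended when any 1 of the 4 polysomal arrays was left out, with between 64 and 104 clones at an unadjusted p under 0.05.

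The log2 ratio against hydrated tissue differed between polysomal and total RNA for 225 clones after slow drying, among annotated clones from the hypothetical protein USD-119 at 3.54 to Toc125 (USD-548) at -2.43, and for 230 after rehydration, among annotated clones from USD-119 at 2.46 to the succinate dehydrogenase subunit (USD-421) at -2.70. Without either array of rapid-dried rehydrated polysomal RNA the 230 became 2, and without 1 slow-dried polysomal array the 225 became 75 or 62, and it became 111 without replicate 2 of slow-dried total RNA and 130 without either array of rapid-dried rehydrated polysomal RNA. After slow drying 36 clones were called in opposite directions in the 2 fractions relative to the typical clone, 18 of them annotated. Among them Tr-217 was low in total and high in polysomal RNA. Tr-288 was the reverse, although above the controls in polysomal RNA on the control scale (0.29). Tr-288 was not well above background in treated polysomal RNA. USD-231, which carries the name of Tr-288, was called higher in both fractions (1.39 in total and 0.83 in polysomal RNA). After rehydration 30 clones were called in opposite directions, 8 of them annotated. Among them succinate dehydrogenase was high in total and low in polysomal RNA, but above the controls there on the control scale (0.51). Ribosomal protein L38 (USD-47) was the reverse. The other L38 clone (USD-194) was called in neither fraction and lay the other way (difference -0.66, limma adjusted p = 0.248). These directions are relative to the typical clone. Fraction and hybridisation batch cannot be told apart here, since the fractions came from separate preparations and slides.

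Most clones stood above the ribosomal protein control clones in treated tissue, in all 4 comparisons. A signal-dependent bias between bright and dim spots would leave clones as bright as the controls near them, but with no loess the lowest of their 4 medians was 1.07. The controls spanned a wide range of signal, so between 342 and 428 clones counted as bright as they. The match is therefore coarse, and a bias within that range is not excluded. Clones with no annotation were not the sole source, since the lowest median of the 187 annotated clones that are not ribosomal was 0.90. In total RNA the 18 other ribosomal protein clones lay close to the controls (the median furthest from 0 was -0.18), so a fall of ribosomal protein transcripts as a class, controls included, may account for the offset there. In slow-dried polysomal RNA they lay above the controls (0.76), which argues against a shared fall as the whole account there. In rapid-dried rehydrated polysomal RNA their median lay at 0.37, and they ran from -0.021 to 1.83. That median is within the 0.5 set for a shared fall, but this limit was set after the result was seen. A shared fall may account for some of the offset in that comparison, and whether it accounts for all of it cannot be told. Whether the typical clone rose or the controls fell stays open.

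Clones with no annotation were over-represented among the higher clones. They made up 83.5% of higher and 61.7% of lower clones in slow-dried total RNA (odds ratio 3.15, Fisher's exact test with Benjamini-Hochberg adjusted p = 3.08e-07), with odds ratios of 2.67, 2.88 and 2.40 in the other comparisons (adjusted p = 1.86e-05, 7.13e-05 and 0.0020). The clones are not independent replicates. Hydrated signal near background is argued against by an odds ratio of at least 2.45 among clones measured in both channels, and lower signal of these clones by a Mantel-Haenszel odds ratio of at least 2.36 within 4 classes of signal. The higher clones may therefore include moss transcripts with no match among named genes. How the annotation was made, which could also favour abundant housekeeping genes, was not tested. Ribosomal protein clones, all annotated, made up 20 of the 235 lower and 0 of the 249 higher clones in slow-dried total RNA. In the other comparisons, in the order above, 17, 14 and 13 were lower and 1, 1 and 2 higher. The odds ratios were not computed without them, nor on the control scale.

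Slide 85 is titled slow-dried, but its source name and protocol say rapid-dried and rehydrated. Its log2 ratios correlated across clones at 0.93 with slide 73 of the latter treatment, against 0.73 and 0.74 with the slow-dried polysomal slides, which argues against the title. The source name is likely right for this slide. No biological explanation was tested.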

How the results depend on the processing

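The signal median, the removal of spots with a flag above 0 and the control shift with no loess were chosen only after the result was seen. In the comparisons with hydrated tissue in total RNA the counts stayed within 1.5 times under all alternatives run, 484 clones (370 to 535 with 1 array left out) and 432 (323 to 465), but their split into higher and lower did not. Counts in polysomal RNA and in the differences depended on single arrays, where the lone array left is assumed to vary like the other groups. With 1 array left out they ran from 129 to 386 for slow-dried and from 0 to 315 for rapid-dried rehydrated polysomal RNA, from 60 to 145 and from 0 to 47 for slow drying against rehydration in total and polysomal RNA, and from 62 to 280 and from 2 to 260 for polysomal against total RNA after slow drying and rehydration. The 0 by limma for rapid-dried rehydrated polysomal RNA held without either of its arrays (180 and 185 at an unadjusted p under 0.05), and the 0 for slow drying against rehydration without any 1 polysomal array (87, 104, 76 and 64). These fits have fewer arrays by construction. For the settings below the cause was not tested unless stated. A fit on 1 fraction for the differences between polysomal and total RNA could not be fitted. Dim signal limits total RNA most, with 91 and 97 clones in the hydrated channel under the limit for slow-dried and rapid-dried rehydrated plants, against 14 and 23 in polysomal RNA.

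Counts that moved by over 1.5 times are given for slow-dried and rapid-dried rehydrated polysomal RNA, slow drying against rehydration in total and in polysomal RNA, and polysomal against total RNA after slow drying and after rehydration, in that order. The control scale gave 647, 590, 89, 0 (172 at an unadjusted p under 0.05 by limma), 146 and 144, and the control shift with no loess 585, 556, 74, 0 (179) and 147 for the first 5. Both move every clone by construction. Dye-swap normalization gave 597 for slow-dried polysomal RNA, 579 for slow drying against rehydration in polysomal RNA and 613 for polysomal against total RNA after rehydration. A fit on 1 fraction gave 528, 480, 59 and 340 for the first 4, array weights 507, 42 and 239 for the last 3 of these, and spots kept separate 288 and 152 for slow drying against rehydration. The authors' ratios gave 0 (152 at an unadjusted p under 0.05), 1 (107), 25 and 0 (223) for the last 4 by limma. Slide 85 read as slow-dried gave 6 (147) for rapid-dried rehydrated polysomal RNA, 28 and 0 (8) for slow drying against rehydration and 16 for the last. The 4 gene list calls became 0 with an estimated correlation by camera and 9 on the control scale with the preset correlation.

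Of 227 values of named clones, 211 kept direction and side of the threshold with no background correction, 224 with plain subtraction, 217 with median centring and 216 with print-tip loess, against 140 on the control scale, 161 with dye-swap normalization and 97 in the authors' ratios. Of the 21 alternatives run on these values only these last 3 turned directions, of 37 values in all, and all but 1 were falls relative to the typical clone. Leaving out 1 polysomal array, or reading slide 85 as slow-dried, took more of these values out of the calls than either change of background did. The 3 settings chosen later were run on counts alone, where the control shift with no loess turned 72, 50, 46 and 5 calls in slow-dried total, rapid-dried rehydrated total, slow-dried polysomal and rapid-dried rehydrated polysomal RNA. On the control scale the turned log2 ratios were as follows. For slow-dried total RNA 0.61 for S16, 1.04 for Tr-418, 0.12 for USD-189, 0.76 for USD-379 and 0.31 for USD-414. For rapid-dried rehydrated total RNA 0.47 for L17, 0.34 for S16, 0.24 for Tr-217, 0.51 for Tr-418, 0.21 for Tr-cpk, 0.023 for USD-189, 0.51 for USD-30, 0.14 for USD-460 and 0.18 for USD-591. For slow-dried polysomal RNA 0.35 for S16, 0.29 for Tr-288, 0.86 for Tr-418, 0.40 for Tr-421, 0.49 for USD-364 and 0.11 for USD-511. For rapid-dried rehydrated polysomal RNA 0.21 for S3, 0.51 for Tr-421, 0.48 for USD-165, 0.61 for USD-189, 0.25 for USD-364, 0.031 for USD-460 and 0.076 for USD-547. With dye-swap normalization they were these. For slow-dried total RNA 0.49 for S16, 0.67 for Tr-418 and 0.76 for USD-379. For rapid-dried rehydrated total RNA 0.089 for L17, 0.59 for S16, 0.16 for Tr-217, 0.56 for Tr-416, 1.02 for Tr-418, 0.27 for Tr-cpk, 0.0047 for USD-129, 0.10 for USD-189, 0.0066 for USD-190, 1.09 for USD-30, 0.47 for USD-379, 0.42 for USD-460 and 0.00081 for USD-547. For slow-dried polysomal RNA 0.10 for S16, 0.51 for Tr-418, 0.011 for Tr-421 and 0.21 for USD-364. For polysomal against total RNA after rehydration it was -0.078 for USD-745. In the authors' ratios the values were the following. For slow-dried total RNA 1.09 for S16, 0.0055 for S3, 0.87 for Tr-418, 0.36 for USD-189, 1.13 for USD-379, 0.26 for USD-414 and 0.25 for USD-511. For rapid-dried rehydrated total RNA 0.11 for L17, 0.44 for S16, 0.085 for Tr-217, 0.66 for Tr-416, 1.17 for Tr-418, 2.61 for Tr-cpk, 0.064 for USD-129, 0.018 for USD-189, 1.12 for USD-30, 0.52 for USD-379, 0.35 for USD-460 and 0.0073 for USD-547. For slow-dried polysomal RNA 0.047 for S14, 0.16 for S16, 0.67 for Tr-418, 0.19 for Tr-421, 0.34 for USD-364 and 0.087 for USD-511. For rapid-dried rehydrated polysomal RNA 0.023 for S14, 0.22 for S3, 0.46 for Tr-421, 0.54 for USD-165, 0.67 for USD-189, 0.27 for USD-364, 0.13 for USD-460 and 0.048 for USD-547.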

Other observations

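The comparisons here were chosen only after the result was seen, as were the clones named, apart from those the report names. Clones with the same annotation did not always move together, relative to the typical clone. Values are log2 ratios in the order slow-dried total, rapid-dried rehydrated total, slow-dried polysomal and rapid-dried rehydrated polysomal RNA, with n = 2 arrays each. The 2 clones annotated as ribosomal protein L38 stood at 0.67, -0.036, -0.31 and -0.70 (USD-194) and at -1.62, -1.36, 1.07 and 0.73 (USD-47). Rehydrin Tr-288 stood at 1.00, 0.37, -1.12 and -0.73, and USD-231, which carries its name, at 1.39, 1.06, 0.83 and 0.16. The 3 clones annotated as Lea protein stood at 1.31, 1.05, 0.34 and 0.98 (USD-161), 0.79, 0.78, -0.26 and -0.57 (USD-165) and -0.18, -0.040, -0.75 and -0.26 (USD-397). The 2 trehalase clones stood at -0.24, 0.87, -0.18 and 0.51 (USD-539) and 0.42, 1.51, -0.53 and 1.06 (USD-578). Whether clones of 1 annotation come from 1 gene was not tested.

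Among annotated clones called higher in all 4 comparisons, beside catalase and the serine decarboxylase, were a proline-rich protein (USD-569, 0.97, 0.43, 1.17 and 0.92) and annexin a7 (USD-715, 0.44, 0.47, 0.57 and 0.54). On the control scale 424 clones were called higher in all 4 comparisons and 0 lower, by limma with Benjamini-Hochberg adjustment. Relative to the typical clone 119 clones were called in none.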
